A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

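RNA from Saccharomyces cerevisiae of the S288C background was sequenced in 6 libraries, 3 from a wild-type strain and 3 from a kap114 knockout strain, all grown in YPD with 1.5 M NaCl. Per the labels' protocols, total RNA was isolated with an RNeasy kit and 2 ug were used for stranded mRNA libraries with poly(A) selection. Groups and replicate numbers were taken from the sample titles. The library names carry other replicate numbers for the knockout (3 to 5) and the word TAF1, whose meaning is not given in the sources used here. They also carry S numbers, 1 to 3 in the wild type and 8 to 10 in the knockout. Any order that these numbers reflect cannot be told apart from genotype.

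The authors deposited counts of reads per gene for each library, which are whole numbers without normalization, per the file headers. The authors also deposited RPKM and TPM values per gene and library, per the file headers. For 95.0% of genes the deposited RPKM equalled the count divided by the region length and library total, within 0.0001. The authors' deposited table of the comparison holds a signed fold change, a log2 fold change, a p-value and a false discovery rate per gene. Later deposited tables hold a ratio of each TPM to the gene's median over the 6 libraries and the log2 of that ratio, for 2212 genes. The submitters' processing notes name FastQC and the genome build R64; the aligner, the counting program and the test behind the deposited p-values are not given in the sources used here. The gene table lists 7125 genes, of which 555 had 0 counts in all libraries. A reference annotation of build R64 was compared with it: 6190 identifiers matched (86.9%), and 6174 of these (99.7%) had identical start and end. Coordinates are those of the gene table. For 43 features nested on the opposite strand of a gene with more than 50 RPKM, the median ratio to that gene was 0.000691 and 97.7% lay under 0.05, so the counts separated the strands.

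Library totals ranged from 33638728 to 38540115 counts. A floor of 3 counts corresponds to 0.0778 to 0.0892 CPM in 1 library. Floors cover counting error only, and the intervals given cover the sampling of genes only. CPM values were scaled with TMM factors, which lay between 1.02 and 1.07 in the wild type and between 0.947 and 0.958 in the knockout.

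Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 6080. Changes were tested with edgeR 4.0.16 (quasi-likelihood fit with robust dispersion, TMM scaling) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05; the common biological coefficient of variation was 0.177. The SE of a log2 fold change was computed from the quasi-likelihood F statistic, and values in CPM are given with the SD over libraries. Without adjustment 4166 genes had a p under 0.05. Gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 on log2 CPM (prior count 2), for lists with at least 5 tested genes, adjusted over 41 lists; p-values with a correlation estimated per list and from fry were computed beside them. Camera compares a list with the other genes, while fry asks whether its genes move one way on balance.

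The groups, the tests, 42 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named KAP114 and its neighbours DOC1 and YGL242C, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 10 CPM in a group and no overlap between groups, up to 4 genes with the smallest p from each list, and all tested genes of the list of karyopherins and cargo. Where no gene of a list passed, up to 2 with the highest expression were named. Genes outside this rule are said to have been named after their values were seen.

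Of the called genes, 403 (10.3%) overlap a gene on the opposite strand, against 731 (12.0%) of the tested ones. Near-identical gene copies, such as those of ribosomal proteins, histones, hexose transporters and glycolytic enzymes, are treated as uncertain.

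The gene test was tested on simulated data with the means and library sizes of the 6080 genes, of which 200 were changed. It recovered 88.7% of the changes of 1 and 100% of those of 2 on the log2 scale, and 19 of its 207 calls were false. A simulated list of 40 genes shifted by 0.5 was called, and 0 of 100 unchanged lists were. Each simulated gene was drawn independently of the others, so these results do not bear on lists whose genes vary together. The simulation also changed a far smaller share of genes than was called in the data.

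The alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), no filter on low counts, a filter of at least 10 CPM in 3 libraries, removal of the 10 most abundant genes, the title's replicate number as a block, and leaving out each library in turn. For the authors' deposited fold changes, DESeq2 and limma on TPM were added as alternatives after the data were examined. Tables were made with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9. Read sequences were not analysed here.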

Results

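Poly(A)-selected RNA was measured by stranded sequencing in Saccharomyces cerevisiae of the S288C background, in a wild-type strain and in a kap114 knockout strain, both grown in YPD, a rich glucose medium, with 1.5 M NaCl. Kap114 is a karyopherin, a transport receptor that carries cargo such as the TATA-binding protein and histones into the nucleus. There were 3 libraries of each genotype, and the comparison asks how the transcriptomes of the 2 genotypes differ in high salt. No library from medium without added salt was analysed here, so no response to salt was measured. The counts summed to 34804321, 37893192 and 33638728 in wild-type libraries 1 to 3 and to 35834253, 34685666 and 38540115 in knockout libraries 1 to 3. The labels do not say whether the libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

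KAP114 itself (YGL241W, chromosome VII, 45445 to 48459, plus strand, build R64) had 257, 336 and 312 counts in the wild-type libraries and 0 counts in each knockout library. The wild-type level was 8.08 ± 0.763 CPM (SD, n = 3), and the level in the knockout was at least 279-fold lower, with 3 counts over the whole group, 0.0289 CPM, taken as the floor. Of the genes on either side, DOC1 (48613 to 49365), which encodes a subunit of the anaphase-promoting complex, had a log2 fold change of -0.13 ± 0.13 (SE) and an adjusted p of 0.389 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. YGL242C (44652 to 45197, minus strand) rose 2.12-fold, from 11.2 ± 1.14 to 23.7 ± 6.35 CPM (SD, n = 3 each).

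In the knockout 136 of 138 genes for cytosolic ribosomal proteins and 19 of 25 for glycolysis and fermentation rose, and 19 of 23 genes for gluconeogenesis and acetate use and 20 of 27 for peroxisomes and fatty acid oxidation fell. Camera called these 4 lists with a preset correlation, and each had an adjusted p = 0.77 with an estimated correlation. Of 6080 tested genes, 3911 (64.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2085 of them higher and 1826 lower in the knockout. A change of at least 2-fold was found for 1505 of these genes, 1041 higher and 464 lower, or 860 higher and 680 lower when only library totals were used for scaling. The median log2 fold change of all tested genes was 0.01, and it was -0.13 when only library totals were used for scaling. The groups did not overlap for 4484 tested genes (73.8%), where chance gives 10%. The number of lower genes depended on single libraries: it was 1211 without wild-type library 1 and 1090 without knockout library 3, and genes lower by at least 2-fold numbered 278 without knockout library 3, 288 without knockout library 2 and 801 without knockout library 1.

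Knockout library 1 stood apart from the other knockout libraries. The first principal component of log2 CPM held 88.0% of the variance and placed the wild-type libraries at -43.0, -29.5 and -35.0, knockout libraries 2 and 3 at 53.0 and 42.4, and knockout library 1 at 12.01. Without this library 4639 genes passed, 2378 higher and 2261 lower. The share of counts on RDN37, the ribosomal RNA precursor locus, also moved with genotype: it was 3.69%, 4.54% and 3.77% in the wild-type libraries and 12.3%, 9.05% and 11.3% in the knockout libraries.

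**Figure D1:**
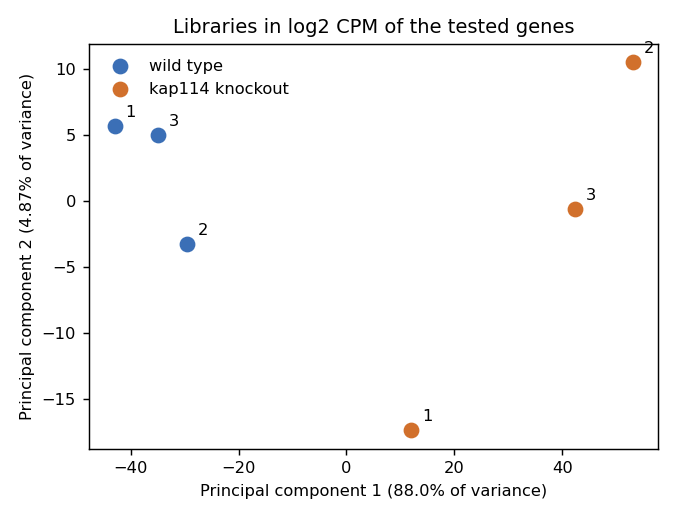
Positions of the 6 libraries on the first and second principal components of log2 CPM over the tested genes, with the share of variance on each axis and replicate numbers beside the points. Wild-type libraries (blue) lie at -43.0, -29.5 and -35.0 on the first component and knockout libraries (orange) at 12.01, 53.0 and 42.4.

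Genes of the cytosolic translation machinery were higher in the knockout. RPS22A (chromosome X, 74910 to 75302), which encodes a protein of the small ribosomal subunit, rose 6.75-fold, from 34.5 ± 9.63 to 233 ± 53.7 CPM (SD, n = 3 each), and RPS17B rose 5.64-fold. Of 138 tested genes for cytosolic ribosomal proteins, 136 rose and 0 fell, with the same counts adjusted over the list alone, a median log2 fold change of 2.05 and an interquartile range of 1.84 to 2.21. RPL15B and RPL41A, named after their values were seen, did not pass, at 0.22 ± 0.11 and 0.44 ± 0.21 (log2, SE). Without knockout library 1 both passed, with edgeR adjusted p of 0.00962 and 0.0371. Many ribosomal protein genes have near-identical copies, and the division of reads between such copies is uncertain. Of 138 genes for ribosome biogenesis, 108 rose and 6 fell (110 and 6 adjusted over the list alone), among them the small nucleolar ribonucleoprotein genes NOP56 (1.93 ± 0.20, log2, SE) and NOP58 (2.02 ± 0.21). Of 34 translation factor genes, 23 rose and 0 fell, also adjusted over the list alone, including TEF4 (2.49 ± 0.28), for a subunit of elongation factor 1, and TIF1 (2.44 ± 0.21), for the RNA helicase eIF4A. The adjusted p of limma's camera with a preset correlation was 1.01e-24, 3.69e-11 and 2.52e-05 for the ribosomal protein, biogenesis and translation factor lists, and each had an adjusted p = 0.77 with an estimated correlation. Set against the wild-type mean, the ribosomal protein list had a median log2 difference of 1.52 in knockout library 1, 2.34 in library 2 and 2.17 in library 3. Of 35 genes for RNA polymerases I and III, 17 rose and 4 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.257). RPA49 and RPA43, for subunits of polymerase I, rose 5.27-fold and 4.96-fold. The 4 that fell, RPA14, RPO31, RPC37 and TFC6, were named after their values were seen, and TFC6 lost its call without wild-type library 2 or 3 or knockout library 2 or 3 (edgeR adjusted p from 0.0691 to 0.129).

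Of 69 genes on the list for mitochondrial ribosomal proteins, 34 fell and 5 rose, with the same counts adjusted over the list alone and a median log2 fold change of -0.26 (camera adjusted p = 0.000857, and adjusted p = 0.77 with an estimated correlation). MRPL28 fell 2.19-fold and MRPL51 1.70-fold. The 5 that rose were MRPL25, MRPL32, MRPL44, MRPL7 and YMR1, named after their values were seen apart from MRPL25; YMR1 encodes a phosphoinositide phosphatase and no ribosomal protein. The call of MRPL7 ended without wild-type library 1 or 3 or knockout library 3 (edgeR adjusted p from 0.0587 to 0.0661), and that of YMR1 without wild-type library 1 or 2 or knockout library 2 or 3 (0.0594 to 0.0742). Of 13 mitochondrially encoded genes, 8 rose and 0 fell, also adjusted over the list alone, including the COX1 intron gene AI1, which rose from 10.5 ± 3.10 to 26.0 ± 3.93 CPM (SD, n = 3 each). Others that rose lay nearer the floor, such as OLI1 (mean 0.298 to 0.972 CPM) and SCEI (0.127 to 0.495 CPM). AI1 and AI2 begin at the same position and SCEI lies inside 21S_RRNA, so the members of the list are not all separate observations. This list had a camera adjusted p of 0.0125, an adjusted p = 0.77 with an estimated correlation, and an adjusted p of 0.0642 without knockout library 1. Its transcripts lack long poly(A) tails, as does RDN37, whose share of counts was 3.69% to 4.54% in the wild-type libraries and 9.05% to 12.3% in the knockout libraries.

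Carbon metabolism genes changed in opposite directions by pathway. ENO2 (chromosome VIII, 451327 to 452640), for the glycolytic enzyme enolase, rose 9.14-fold, from 645 ± 133 to 5897 ± 2554 CPM (SD, n = 3 each), with an adjusted p of 0.00114 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. TDH2, for glyceraldehyde-3-phosphate dehydrogenase, rose 8.51-fold, PGK1 7.04-fold, TPI1 6.72-fold and HXK2, for a hexokinase, 6.73-fold. Of 25 genes for glycolysis and fermentation, 19 rose and 3 fell (20 and 3 adjusted over the list alone), with a median log2 fold change of 2.45 (camera adjusted p = 0.000415, and adjusted p = 0.77 with an estimated correlation). The 3 that fell, named after their values were seen, were GLK1, PYK2 and PDC6, for a glucokinase, a pyruvate kinase and a pyruvate decarboxylase. GLK1 was more abundant than HXK2 in both groups, at 4907 ± 685 CPM in the wild type and 2848 ± 480 CPM in the knockout against 126 ± 18.9 and 848 ± 296 CPM (SD, n = 3 each). The call of GLK1 ended without any 1 library other than knockout library 1 (edgeR adjusted p from 0.0564 to 0.102), and that of PDC6 without wild-type library 1 or 3 or knockout library 2 or 3 (0.0620 to 0.0827). Glycolytic genes also have near-identical copies, such as TDH2 and TDH3 or ENO1 and ENO2, for which the division of reads is uncertain. The list's median difference from the wild-type mean was 1.88, 2.79 and 2.47 in knockout libraries 1 to 3. Of 18 hexose transporter genes, 6 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.925): HXT3 rose 4.41-fold and HXT1 3.44-fold, both for low-affinity transporters, while HXT13 fell 1.97-fold.

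Of 23 genes for gluconeogenesis, the glyoxylate cycle and acetate use, 19 fell and 3 rose, also adjusted over the list alone, with a median log2 fold change of -1.21. FBP1, for fructose-1,6-bisphosphatase, fell 3.09-fold, from 109 ± 6.34 to 35.3 ± 8.61 CPM (SD, n = 3 each), and MLS1, for malate synthase, fell 2.31-fold. The 3 that rose were DAL7, ACS2 and ALD5, the last named after its values were seen; ACS2 encodes the acetyl-CoA synthetase used during growth on glucose. Of 27 genes for peroxisomes and fatty acid oxidation, 20 fell, including SPS19 (2.01-fold lower), and 2 rose, ANT1 (1.01 ± 0.11, log2, SE) and FAA4 (1.36 ± 0.20), also adjusted over the list alone. Of 28 genes for the tricarboxylic acid cycle, 15 fell (16 adjusted over the list alone). IDP2, for the cytosolic isocitrate dehydrogenase, fell 4.01-fold, while PYC2, FUM1 and LSC1, named after their values were seen, rose; LSC1 had an edgeR adjusted p of 0.0502 without wild-type library 1. Of 42 nuclear genes for oxidative phosphorylation, 18 fell and 1 rose (16 and 1 adjusted over the list alone). NDE2, for an external NADH dehydrogenase, fell 4.29-fold and SDH2 2.17-fold; ATP5, named after its values were seen, rose, with an edgeR adjusted p of 0.0503 without wild-type library 3. Camera's adjusted p was 0.000576 for the gluconeogenesis and for the peroxisome list, 0.00933 for the tricarboxylic acid cycle and 0.00290 for oxidative phosphorylation, and each list had an adjusted p = 0.77 with an estimated correlation. The median difference of the gluconeogenesis list from the wild-type mean was -0.78 in knockout library 1, -1.92 in library 2 and -1.31 in library 3.

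**Figure D2:**
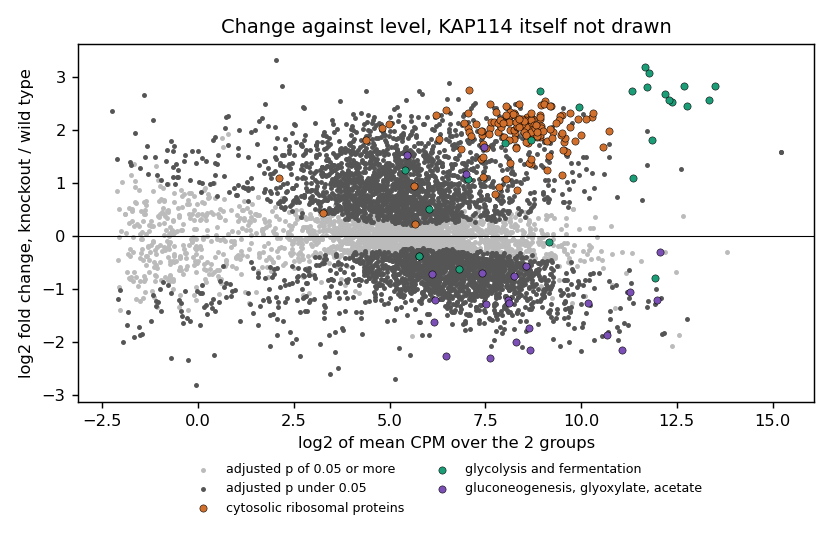
Log2 fold change of each tested gene, knockout over wild type, against the log2 of its mean CPM over the 2 groups, with genes past an adjusted p of 0.05 in dark grey. Genes for cytosolic ribosomal proteins (orange, median 2.05) and glycolysis and fermentation (green, median 2.45) lie mostly above 0, and genes for gluconeogenesis, the glyoxylate cycle and acetate use (purple, median -1.21) mostly below.

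Stress and salt genes did not move as one block. Of 50 targets of the general stress factors Msn2 and Msn4, 24 fell and 6 rose, also adjusted over the list alone (5 fell and 4 rose without knockout library 3), with a median log2 fold change of -0.68 (camera adjusted p = 0.00408, and adjusted p = 0.77 with an estimated correlation). RIM4 (-1.59 ± 0.22, log2, SE) and TMA17 (2.02-fold) fell, while GPH1, for glycogen phosphorylase, rose 2.77-fold and YGP1 2.55-fold. The median difference of this list from the wild-type mean was -0.30 in knockout library 1, -0.996 in library 2 and -0.70 in library 3. Of 32 genes of the osmotic stress pathway through Hog1 and of glycerol metabolism, 10 rose and 8 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.906). YPD1, SHO1 and SSK22, upstream members of the pathway, rose 2.04-fold, 1.94-fold and 2.39-fold, and HOT1, for a transcription factor activated by Hog1, fell 1.80-fold. The genes for glycerol synthesis GPD1 and GPP2, named after their values were seen, rose 2.33-fold and 3.13-fold. The hydrophilin genes SIP18 and GRE1, also named after their values were seen, spread widely: SIP18 had 4898, 333 and 910 CPM in knockout libraries 1 to 3 against 8624 ± 444 CPM in the wild type (SD, n = 3). Neither passed (adjusted p = 0.0708 and 0.0597 in edgeR's quasi-likelihood test). Both passed without knockout library 1 (2.27e-05 and 4.49e-05) and with DESeq2 (0.0245 and 0.0356).

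Of 26 genes for sodium, potassium and proton transport and its regulation, 11 fell and 8 rose, also adjusted over the list alone (camera adjusted p = 0.477). PMA1, for the plasma membrane proton pump, rose 4.94-fold, from 356 ± 57.7 to 1762 ± 509 CPM (SD, n = 3 each), and TRK1, for a potassium transporter, rose 1.99-fold. PHO89 and TRK2, for a sodium-phosphate cotransporter and a potassium transporter, fell 3.16-fold and 2.81-fold; both were named after their values were seen. The sodium pump genes ENA1, ENA2 and ENA5 are near-identical copies, so their values are uncertain: ENA2 rose 3.78-fold to 169 ± 47.4 CPM and ENA5 1.66-fold to 96.1 ± 10.5 CPM, whereas ENA1, the most abundant of the 3 and like ENA5 named after its values were seen, fell 1.86-fold to 1768 ± 399 CPM (SD, n = 3). The call of ENA1 ended without wild-type library 1 and without knockout library 3, at edgeR adjusted p of 0.0621 and 0.0750.

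Among karyopherins and the known or possible cargo of Kap114, several other karyopherin genes rose. Of 23 tested genes on this list, 11 rose and 7 fell, KAP114 included, also adjusted over the list alone. KAP122, PSE1, MTR10, KAP123, SXM1, CSE1, which encodes the exporter of importin alpha, KAP104 and NMD5 rose by 0.49 to 1.22 on the log2 scale. LOS1 (1.06 ± 0.19, log2, SE), for a tRNA exporter, and MOT1 (0.36 ± 0.13) also rose. GSP1, for the small GTPase Ran, rose 3.79-fold, from 103 ± 14.6 to 389 ± 112 CPM (SD, n = 3 each), while its near-identical copy GSP2 fell 2.08-fold, with 203, 74.3 and 92.3 CPM in knockout libraries 1 to 3. SPT15 (chromosome V, 465303 to 466025), which encodes the TATA-binding protein, fell 1.54-fold, from 305 ± 11.2 to 198 ± 36.0 CPM. NAP1, for a histone chaperone, fell 1.52-fold and SUA7, for the initiation factor TFIIB, 1.66-fold, and the karyopherin genes MSN5 and CRM1, for other export receptors, also fell. KAP95, SRP1, KAP120, BUR6 and NCB2 did not pass, at log2 fold changes from -0.10 to 0.16, although KAP95 had an edgeR adjusted p of 0.0462 with scaling by library totals only. Without knockout library 3, the calls of SPT15, NAP1, MSN5, SUA7, CRM1, GSP2 and MOT1 ended, with edgeR adjusted p of 0.0520, 0.0523, 0.0640, 0.0777, 0.0931, 0.105 and 0.130. Apart from SPT15, each of these calls also ended without at least 1 other library, with adjusted p of up to 0.141 for MOT1 without wild-type library 1. The list did not pass (camera adjusted p = 0.620).

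Of 29 genes for subunits of TFIID and SAGA, coactivators that bind the TATA-binding protein, 10 fell and 6 rose, also adjusted over the list alone (camera adjusted p = 0.735). SPT8 fell 1.89-fold and TAF13 1.35-fold, and TRA1 and TAF11 rose 1.60-fold and 1.48-fold. TAF1, named after its values were seen because it appears in the library names, fell 1.94-fold; its call ended without wild-type library 3 and without knockout library 3, at edgeR adjusted p of 0.0521 and 0.0599. Of 10 histone genes, 2 rose, HTA2 (3.49-fold) and HTB2 (2.62-fold), and 2 fell, HHO1 (2.42-fold) and HHT1 (1.75-fold), also adjusted over the list alone (camera adjusted p = 0.918).

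**Figure D3:**
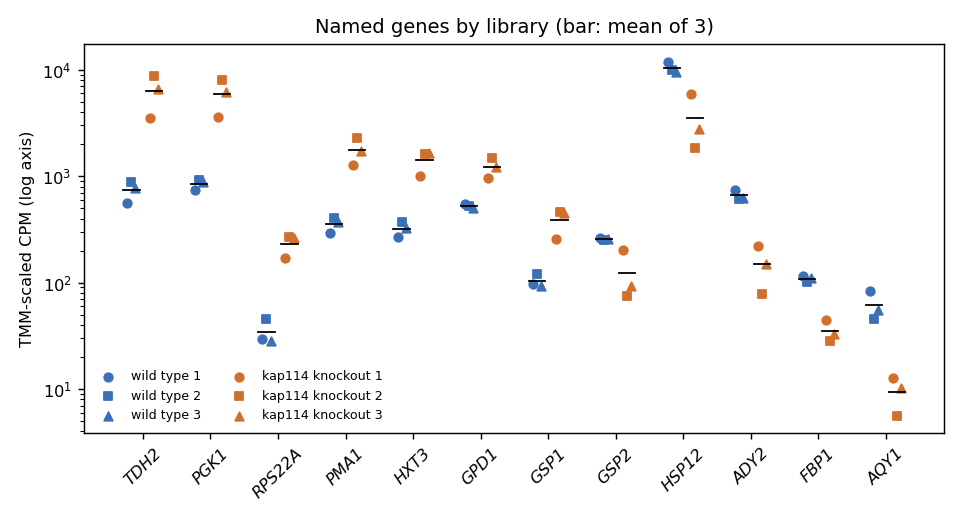
TMM-scaled CPM of 12 named genes in each library, on a log axis, with a bar at the mean of 3 libraries. Knockout library 1 (orange circles) lies between the wild-type libraries (blue) and the other knockout libraries for TDH2, GSP2, HSP12 and ADY2. HSP12 was named after its values were seen. Its call ended without wild-type library 1 and without knockout library 3, at edgeR adjusted p of 0.0586 and 0.0736.

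Of 45 cell cycle genes, 35 rose and 6 fell (38 and 6 adjusted over the list alone), with a median log2 fold change of 1.05. The mitotic cyclin genes CLB2 and CLB1 rose 5.87-fold and 4.76-fold, and SWI5, for a transcription factor of late mitosis, 4.55-fold. Of 62 amino acid biosynthesis genes, 42 rose and 9 fell (44 and 9 adjusted over the list alone), including HOM3 (4.22-fold higher), for aspartate kinase, and ARO8 (4.82-fold). Of 22 genes for purine synthesis, 16 rose and 1 fell (16 and 2 adjusted over the list alone). IMD2, for inosine monophosphate dehydrogenase, rose 5.71-fold; the 1 that fell, ADE16, was named after its values were seen and lost its call without any 1 library other than knockout library 1 (edgeR adjusted p from 0.0587 to 0.137). Of 27 ergosterol synthesis genes, 19 rose and 4 fell, also adjusted over the list alone. ERG26 (2.07 ± 0.23, log2, SE) and ERG13 (3.25-fold) rose, and the 4 that fell, ERG7, HMG2 and the regulators UPC2 and ECM22, were named after their values were seen; HMG2 lost its call without any 1 library other than knockout library 1 (edgeR adjusted p from 0.0634 to 0.166). Of 48 cell wall genes, 28 rose, such as GAS1 (4.03-fold) and EXG1 (3.50-fold), and 3 fell, FIT1, GSC2 and YPS1, also adjusted over the list alone and named after their values were seen. GSC2 lost its call without knockout library 3 (edgeR adjusted p = 0.0685) and without wild-type library 1 (0.0523). Camera's adjusted p was 1.34e-05 for the cell cycle, 0.000576 for amino acids, 0.00581 for purines, 0.00649 for ergosterol and 0.00855 for the cell wall, with an adjusted p = 0.77 with an estimated correlation for each; the cell wall list had 0.0645 without knockout library 1. In knockout libraries 1 to 3 the cell cycle list had a median difference from the wild-type mean of 0.81, 1.20 and 1.11.

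Of 29 genes for autophagy and vacuolar proteases, 19 fell and 2 rose, APE1 and YSP3, also adjusted over the list alone, YSP3 being named after its values were seen. ATG4 fell 2.25-fold and ATG19 1.70-fold. Of 35 proteasome genes, 11 fell and 2 rose, but adjusted over the list alone 3 fell and 0 rose. RPN10 fell 1.77-fold; the 2 that rose, PRE2 and PRE9, lost their calls without knockout library 3 (edgeR adjusted p = 0.0595 and 0.126) and without each wild-type library in turn, and PRE9 was named after its values were seen. The autophagy and proteasome lists had camera adjusted p of 0.000684 and 0.0164, and each had an adjusted p = 0.77 with an estimated correlation. Of 8 genes specific to mating type a, 6 rose and 0 fell (7 and 0 adjusted over the list alone), including AGA2 (2.29-fold) and STE2 (1.60-fold), with a camera adjusted p of 0.0407 and an adjusted p = 0.77 with an estimated correlation. That list no longer passed without knockout library 1 (camera adjusted p = 0.153), wild-type library 1 (0.0523) or wild-type library 3 (0.0566). None of the 4 tested genes specific to mating type alpha passed edgeR's test at an adjusted p of 0.05, and SAG1 and STE3 had log2 fold changes of -0.02 ± 0.23 and -0.05 ± 0.41 (SE). SAG1 had 38.5 ± 3.85 CPM in the wild type and 38.0 ± 12.3 CPM in the knockout (SD, n = 3 each). STE6, which is specific to mating type a, had 38.0 ± 8.32 CPM in the wild type (SD, n = 3). CPM is not scaled by gene length, and STE6 is the longer gene, so per unit of length SAG1 was higher than STE6. STE2 is shorter than SAG1 and had 54.2 ± 8.15 CPM in the wild type (SD, n = 3), so per unit of length STE2 was higher than SAG1. STE3, specific to mating type alpha, had 1.60 ± 0.281 CPM in the wild type (SD, n = 3). Single genes therefore do not rank the mating types.

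**Figure D4:**
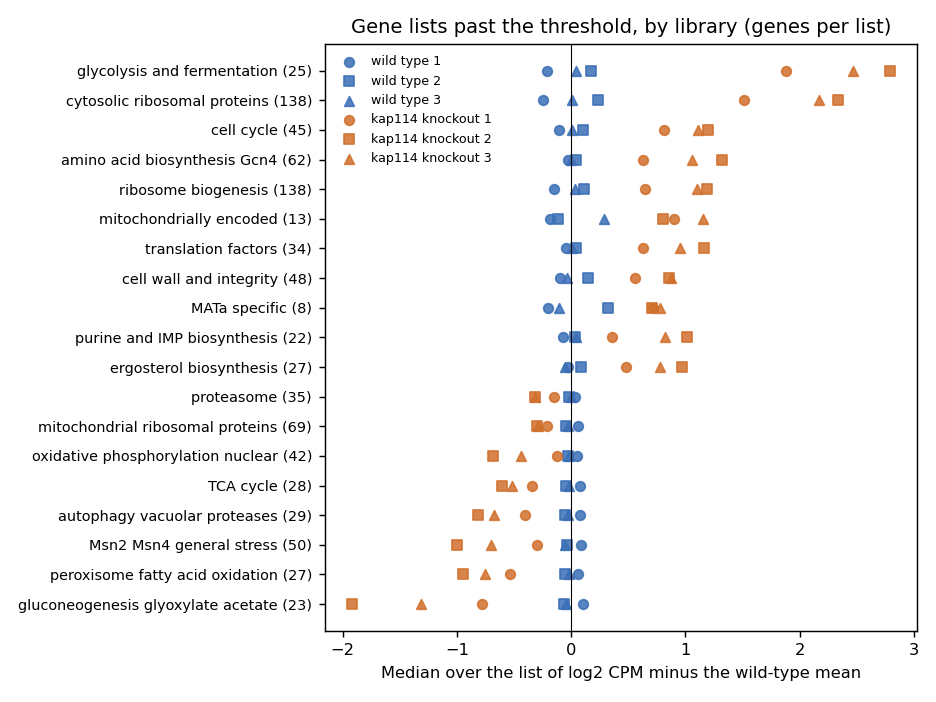
Median over each gene list of log2 CPM minus the wild-type mean of the gene, for the 19 lists past a camera adjusted p of 0.05 with a preset correlation, with the number of tested genes in parentheses. Knockout library 1 lies nearer to 0 than knockout libraries 2 and 3 for most lists, at 1.52 against 2.34 and 2.17 for cytosolic ribosomal proteins.

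Of the genes with a mean of at least 10 CPM in a group and no overlap between groups, the 10 largest increases also included IRC7 (7.45-fold), for a cysteine desulfhydrase, FBA1, GPM1 and BSC1. The 10 largest decreases were led by AQY1 (chromosome XVI, 921860 to 922777), for a water channel, which fell 6.49-fold from 61.5 ± 19.1 to 9.47 ± 3.56 CPM (SD, n = 3 each). They also held YAT1, for a carnitine acetyltransferase (4.94-fold lower), SFC1, for a mitochondrial succinate-fumarate carrier (4.81-fold), ADY2, for an acetate transporter (4.43-fold), BSC4 (5.64-fold) and SPG1, a gene named for survival in stationary phase (4.52-fold). The other 4 were the small or dubious reading frames YPL119C-A, YAL042C-A, OPI9 and YGR022C, of which the last 3 overlap a gene on the opposite strand. The calls of OPI9 and SPG1 ended without knockout library 3 (edgeR adjusted p = 0.0871 and 0.0844) and without wild-type library 1 (0.0826 and 0.0648) or 3 (0.0706 and 0.0664), and that of OPI9 also without wild-type library 2 (0.0640).

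Camera with a preset correlation called 19 of 41 tested lists, 11 higher and 8 lower, and 0 lists with an estimated correlation, where 0 lists also had an unadjusted p under 0.05 and the smallest was 0.0788. Limma's fry called 24 lists, but not 2 of these 19, Msn2 and Msn4 targets (fry adjusted p = 0.149) and nuclear genes for oxidative phosphorylation (0.1005). The remaining lists did not pass with camera, and where 5 or fewer of their genes rose or fell these are named, many after their values were seen. Of 36 heat shock and chaperone genes, 17 rose, such as SSB1 (4.68-fold), and 5 fell (SSA3, HSP32, HSP33, APJ1 and CDC37; camera adjusted p = 0.176). Oxidative stress had 12 higher and 11 lower of 35 (0.922), with TRX1, for thioredoxin, 3.39-fold higher. Trehalose and glycogen had 4 higher (TPS3, GSY1, GPH1 and PGM1) and 7 lower of 20 (0.614), and the unfolded protein response 9 higher and 2 lower (HRD1 and EPS1) of 18 (0.244). Sulfur assimilation and methionine had 5 higher (MET3, MET14, MET16, SAM1 and CYS3) and 12 lower of 30 (camera adjusted p = 0.171, but 0.0200 without knockout library 3). Nitrogen use had 13 and 12 of 31 (0.774), the phosphate regulon 8 and 6 of 22 (0.922), metal regulons 8 and 17 of 37 (0.176) and thiamine and other vitamins 7 and 8 of 26 (0.925). Anaerobic and seripauperin genes had 11 higher and 3 lower (DAN4, AUS1 and ROX1) of 36 (8 and 2 adjusted over the list alone; camera adjusted p = 0.613). Flocculation and daughter-cell genes had 9 higher and 4 lower (FLO5, FLO9, FLO10 and STE12) of 20 (0.297). The mating pheromone response had 11 and 1 of 34 (0.128, but 0.0142 without wild-type library 2), the 1 lower gene being FUS3, for a mating kinase. Haploid-specific genes had 3 higher (STE4, FAR1 and HO) and 2 lower (FUS3 and STE12) of 11 (0.930). Meiosis and sporulation had 5 higher (SPO13, SPO21, MEI4, SSP1 and SSP2) and 11 lower of 42 (4 and 11 adjusted over the list alone; camera adjusted p = 0.176, but 0.00645 among genes with at least 10 CPM in 3 libraries). Auxotrophic marker genes had 3 higher (LYS2, ADE2 and CAN1) and 2 lower (TRP1 and LYP1) of 6 (0.831). Without knockout library 3 the calls of SSA3, CDC37, GSY1, MET3, MET14, MET16, AUS1, ROX1, FLO9, SPO21, SSP2 and LYP1 ended, with edgeR adjusted p from 0.0526 for MET16 to 0.142 for MET3. The same calls and that of ADE2 ended without wild-type library 1 (0.0558 for ADE2 to 0.132 for MET3). Without wild-type library 2 or 3 or knockout library 2 the calls of AUS1, GSY1, LYP1 and MET3 ended in each case, with values of up to 0.160 for AUS1. Those of FLO9, SSP2, SPO21, CDC37, MET14 and ADE2 ended without at least 1 of these 3. Except where given, counts adjusted over the list alone were the same. For 7 lists that did not pass, the median, the mean and camera's direction differed in sign: karyopherins, TFIID and SAGA, histones, oxidative stress, hexose transporters, vitamins and haploid-specific genes.

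The authors' deposited table gives fold changes of the same comparison. Of 6080 genes, 6077 had the same sign there as in edgeR's fit (99.95%, 95% Clopper-Pearson interval 99.86% to 99.99%), and across genes, which are not independent replicates, Pearson's r and Spearman's rho were 0.999998 each. Both sets of fold changes rest on the same libraries, and the median absolute difference was 0.000781 on the log2 scale. Their closeness is therefore no independent evidence of the changes. In the authors' deposited table, 3619 of the tested genes had a false discovery rate under 0.05; 3527 of these passed edgeR's test, which called 384 further genes, while 92 were called by the authors alone. A shorter list of genes in the authors' deposited table equals the genes with a p under 0.05, a change of more than 1.5-fold and more than 10 TPM in every wild-type library. This last criterion refers to the wild type only. It left out 760 of the 2972 genes of the authors' deposited table that met the other criteria, 641 of them higher and 119 lower in the knockout, and the genes kept were 1056 higher and 1156 lower. Of the 641, 302 had more than 10 TPM in every knockout library, as did 0 of the 119 in the authors' deposited values. The 119 were lower in the knockout and did not exceed 10 TPM in every wild-type library, so their 0 was nearly fixed by the criteria.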

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

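The comparisons of the authors' deposited fold changes with DESeq2 and with limma on TPM were chosen after the result was seen; the other alternatives were planned. The number of changed genes was 3911 and ranged from 3589 (genes with at least 10 CPM in 3 libraries) to 4191 (DESeq2) over the alternatives that keep all libraries, and from 2819 to 4639 with 1 library left out. Higher genes numbered 1729 to 2378 and lower genes 1090 to 2261 with 1 library left out, the latter 1211 without wild-type library 1 and 1090 without knockout library 3, where groups have fewer libraries. Genes changed at least 2-fold numbered 1194 to 2031 in these fits. Between 71.8% and 99.5% of the calls were kept when a library was left out, and 0 calls took the opposite direction in any of these settings. Scaling by library totals only gave 1763 higher and 2297 lower genes, 43.4% higher against 53.3% with TMM. Camera called 19 lists, 16 to 20 with 1 library left out, and 0 with an estimated correlation, where cytosolic ribosomal proteins had an adjusted p of 0.770; fry called 24 lists, but not 2 of the 19, Msn2 and Msn4 targets (adjusted p = 0.149) and oxidative phosphorylation (0.1005). Fry called karyopherins and cargo lower (adjusted p = 0.0136), the opposite of camera's direction, for a list that camera did not call. The list holds KAP114, the deleted gene, whose fall was set by the knockout and pulls the list down. The list's median log2 fold change was 0.16 and its mean -0.25, and 11 genes rose while 7 fell. Fry's call is therefore no evidence that karyopherin genes fell, and the list was not tested without KAP114. For DESeq2 and limma-voom the list test was that of edgeR, so they say nothing about it. The sign of the authors' deposited fold changes was the same for 98.7% of genes with DESeq2 and for 96.5% with limma on log2(TPM + 1), against 99.95% with edgeR; the cause was not tested. Of 291 named genes, 249 were called, and 38 of these lost the call with at least 1 library left out. The title's replicate numbers as a block gave 3916 genes, 2059 higher and 1857 lower, and 18 lists, MATa-specific genes being the list lost (adjusted p = 0.0518). Nothing in the labels says that these numbers pair libraries. Deviations of same-numbered libraries correlated across genes at 0.32, 0.18 and -0.07, and wild-type library 2 correlated best with knockout library 3 (0.26), so the block was not used elsewhere. The depth limits statements on genes near the floor of 0.0778 to 0.0892 CPM per library.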

Other observations

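The tests on knockout library 1, on abundant genes, on the position of ribosomal protein genes, on RNAs without poly(A) tails and on TATA boxes, and the 3 gene lists of the next paragraph, were chosen or had their criteria written after the result was seen.

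Genes for cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher in the knockout: 17 of 18 rose and 0 fell, also adjusted over the list alone, with a median log2 fold change of 1.94. KRS1, for the lysine enzyme, rose from 93.7 ± 19.5 to 528 ± 168 CPM (SD, n = 3 each), and ALA1 did not pass, at -0.10 ± 0.13 (log2, SE). Camera's p was 9.46e-07 (2.84e-06 adjusted over the 3 lists) with a preset correlation and 0.245 (0.544) with an estimated one. Of 11 genes linked to stationary phase, 8 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -1.86. SPG4 had 7118 ± 460 CPM in the wild type and 3763, 764 and 1439 CPM in knockout libraries 1 to 3, while RGI1 rose 2.72-fold. Camera's p was 0.00645 (0.00967 adjusted) and 0.363 (0.544) with an estimated correlation. This list was drawn up from genes seen in these libraries and is not independent evidence of its direction. Of 29 nuclear pore genes, 13 rose and 7 fell (14 and 7 adjusted over the list alone). Camera's p was 0.328, also adjusted over the 3 lists, and 0.608 with an estimated correlation. NUP188 rose from 9.34 ± 1.24 to 38.6 ± 9.30 CPM and NUP42 fell from 81.4 ± 5.83 to 40.5 ± 7.92 CPM (SD, n = 3 each).

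LEU2 had 6, 16 and 21 counts in knockout libraries 1 to 3 and 0 in each wild-type library, and URA3 and MET17 had 0 counts in all 6 libraries. HIS3 had 22461 to 29413 counts.

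Knockout library 1 lay between the wild type and the other knockout libraries: over 1920 genes its median position was 0.594, with 0 at the wild type and 1 at the mean of the other knockout libraries. Wild-type RNA in this library would need a share of 47.4%, but its 0 KAP114 reads allow at most 1.09%, and 130 such reads would be needed. Its depth of 35.8 M counts lay inside the range of the other libraries. A state of the cultures that varies within a genotype may explain the position but stays open, as does a difference in library preparation. Wild-type library 2 minus 1 correlated with knockout minus wild-type library 3 across genes at r = 0.50 (95% bootstrap interval over genes 0.45 to 0.55). Wild-type library 3 minus 1 correlated with knockout minus wild-type library 2 at 0.30, and 3 minus 2 with knockout minus library 1 at -0.21. The sign follows only from the order of subtraction, and genes are not independent replicates.

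Genes for cytosolic ribosomal proteins were higher in the knockout, with a list median of 2.05. A trend with the length and GC content of the annotated regions, introns included, does not account for the whole, since the median was 1.84 after its removal. The length and GC content of the coding sequence alone were not tested. The 10 most abundant genes, 0 of them on the list, left 90.6% of the counts in the wild type and 80.8% in the knockout, which would move all other genes by -0.17 on the log2 scale, against the direction of the list, and the list median was 1.90 with library totals only. Whether the state that separates the knockout libraries also sets the level of these genes cannot be told apart from the genotype, which stays open as a biological explanation, because state and genotype move together. On this list knockout library 1 stood at 0.668, and 138 genes were lower in it than in both other knockout libraries, while 136 were above every wild-type library.

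RNAs without long poly(A) tails were higher in the knockout. All 5 features examined, both RDN37 copies, SNR17A, SNR17B and 21S_RRNA, were higher in each knockout than in each wild-type library, RDN37-1 by 1.59 ± 0.30 (log2, SE). Less complete poly(A) selection in the knockout libraries and a rise of these RNAs themselves would each give this order in 5 of 5 features, so the 2 cannot be told apart. The RDN37 copies are near-identical, as are the SNR17 genes, so these are fewer than 5 independent observations.

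Loss of an importer of the TATA-binding protein might have moved genes with a TATA box as a class. For 1152 tested genes with TATAWAWR between 200 and 50 bp upstream of the start codon, camera's p was 0.998. Their median log2 fold change was 0.03 and that of 4585 other genes 0.02, and 33.5% of the former rose and 28.9% fell, against 35.9% and 30.8% of the latter. Across the alternatives camera's p ranged from 0.814 to 0.999. Camera asks only for a net shift in one direction, so it would miss genes that moved both ways. The shares that rose and fell were not tested.

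With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3911 genes and 1505 with at least a 2-fold change, and it was the 1 split with as many. The highest of the other splits by edgeR was 0 for both counts, with 0 to 104 genes at an unadjusted p under 0.05. Each of the other splits mixes the genotypes, so the difference between genotypes counts as spread within groups and keeps their calls few. Their low counts were thus fixed in advance and say nothing on what caused the changes in the real split.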
